A study of Agaricus bisporus with 16 samples.

How the data were processed

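Compost samples colonised by A. bisporus were collected from cultivation crates 27 and 39 days after spawning, at pinning and at the first flush, per the labels' protocols. Total RNA was extracted by caesium chloride gradient centrifugation from duplicate compost samples and sequenced after standard Illumina library preparation, per the labels' protocols. The groups were the 4 strains (A15, 219 30P, 245 AMA-7 and 065 BP-8) on each day, 8 groups with 2 libraries each, taken from the sample titles.

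The submitters' processing notes name BWA, Bowtie and RSEM. Their versions, what each was used for and the genome build are not given in the sources used here. The values deposited by the authors were read as FPKM, normalized within each library per kilobase of transcript and by the library's mapped fragments. This unit was inferred: the deposited values have 2 decimals and sum to 832823 to 913010 per library, where TPM would give the same sum in each library and counts would be larger. The A15 files list 9520 genes and the files of the other strains 10438. No gene listed for A15 is at 0 in all 4 A15 libraries, whereas 775 of the 10438 genes are at 0 in all 12 other libraries. The 918 genes absent from the A15 files were left out of the tests; 729 of them are at 0 in all 12 other libraries and 16 have a mean of 1 FPKM or more there. The A15 tables were thus made or filtered separately, and this is confounded with strain.

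Gene identifiers were matched to locus tags of the assembly Agabi_varbisH97_2, which was used for names and for which genes neighbour each other only. Of 10438 identifiers 10373 matched (9457 of the 9520 in the A15 files), and 88 genes carry a symbol. No coordinates are given because the files name no build. Depth was estimated from low FPKM values (0.15 to 0.8), which fall in whole-read steps. Relative depth ranged from 0.889 to 1.000, and 1 read in a gene of 1 kilobase was put at 0.113 to 0.128 FPKM, from gene lengths that include introns. Since the count per gene is not known, no counting intervals are given and no count-based test was run.

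Differences were computed from these FPKM as log2(FPKM + 1) for the 8818 genes with a mean of 1 FPKM or more over the 16 libraries. They were tested with limma 3.58.1 in R 4.3.3 (limma-trend, 1 mean per group, all 16 libraries sharing a spread), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The model left 8 residual degrees of freedom and estimated 4.16 prior degrees of freedom, with a median residual SD of 0.15. The contrasts were day 39 against day 27 in each strain and in the mean of the 4 strains, each other strain against A15 on each day, an F test among the 3 non-A15 strains and an F test of strain differences in the day effect. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots. The replicate numbers were not treated as pairs, because no label says that equal numbers mark a shared crate, batch or day. In a check on the data, deviations of replicates with the same number did not go together (28 group pairs, correlations of -0.27 to 0.17).

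The comparisons, their tests, the gene lists by product text and the alternatives were chosen before the data were examined, except for the alternative with absent genes at 0 and those tests of the closing section that are marked there as chosen later. Named genes had to pass the test, reach a mean of 10 FPKM in the higher group and show no overlap between the libraries compared, with genes that have a name ranked first. The rule took the 10 largest rises and falls of the mean day contrast with the same sign in all 4 strains, the 4 largest each way within a strain, and the 6 highest and lowest against A15 on both days. It also took the 6 widest ranges among non-A15 strains, the 6 smallest p-values for strain differences in the day effect, and up to 4 members per list. The text describes part of these genes and says where a gene was chosen after its values were seen.

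Of 23 gene lists fixed by product text, 22 have no members, since the reference table gives symbols and no product descriptions. They cover laccases and multicopper oxidases, class II haem peroxidases, GMC oxidoreductases, cellulose-acting enzymes, cellulose-binding modules, xylan-acting and pectin-acting enzymes, chitin and cell wall enzymes, sugar transporters, sugar alcohol and pentose metabolism, glycolysis and the TCA cycle, proteases (all, subtilisin-type and aspartic), hydrophobins, cytochrome P450s, antioxidant enzymes, nitrogen assimilation, ribosomal proteins, mitochondrially encoded genes, cell cycle genes, and transposable element and viral genes. The remaining list, heat shock proteins and chaperones, found hspA to hspE by symbol. Groups by symbol (complexes I to IV, ATP synthase, all oxidative phosphorylation, alternative respiration, laccases, two-component signalling, phenylpropanoid enzymes, catalases) were written after the reference table was seen and before any test. Lists with 5 or more members were tested with limma's camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over 63 tests.

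The tests were run on simulated data with 200 of 8818 genes changed. These were drawn from genes above the lowest levels, far fewer changed than were called in the data, and no shift of all genes was simulated. The shares below may therefore not hold for genes near the filter or for the real data. For the day contrast in A15, 56.7%, 82.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 6% of calls were false. For the mean day contrast these shares were 85.1%, 98.5% and 100%, with 5% false. For 219 30P against A15 on day 27 they were 53.7%, 82.1% and 97%, with 5.5% false. For the strain difference in the day effect they were 16.4%, 58.2% and 89.4%, with 4.4% false. With nothing changed, 1 gene was called in 219 30P against A15 on day 39 and 0 in the other tests.

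The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 10 FPKM, median-ratio scaling, quantile normalization, the robust option of limma, a replicate block, leaving out each library, leaving out the A15 libraries, fits on only the 4 libraries compared, and a fold threshold of 2. Keeping the 918 genes at 0 FPKM in A15 was added after the data were seen.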

Results

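Messenger RNA was sequenced from compost colonised by mycelium of the button mushroom, Agaricus bisporus. The samples came from A15, the commercially cultivated strain, and from the strains 219 30P, 245 AMA-7 and 065 BP-8. Each strain was sampled 27 days after spawning, when mushroom primordia (pins) formed, and 39 days after spawning, at the first flush of mushrooms. There were 2 libraries for each of the 8 groups of strain and day, 16 libraries in all. The stated purpose of the series was to compare gene expression between strains and life cycle stages, with an eye to compost components that A15 uses poorly.

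The files hold 1 value per gene and library, read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library). They give no read counts. The values sum to between 832823 and 913010 FPKM per library. From the steps between low values, 1 read in a gene of 1 kilobase was estimated at 0.113 to 0.128 FPKM. The libraries thus differed little in depth. Ratios of low values between libraries put the range of relative depth at 1.12-fold. Between 8488 and 8797 genes per library stood at 1 FPKM or more. All tests below used 8818 genes with a mean of at least 1 FPKM over the 16 libraries. Changes are differences of log2(FPKM + 1) with the standard error from limma, with 2 libraries per group, and p-values are adjusted by the Benjamini-Hochberg method (BH). Nothing in the labels says whether the duplicate compost samples came from separate crates, so the p-values measure only the spread between these samples, which may be technical in part.

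Day of sampling separated the libraries more than strain did. Across genes, which are not independent replicates, the Spearman correlation had a median of 0.992 between replicates of a group. It was 0.927 between different non-A15 strains on the same day, 0.922 between A15 and another strain on the same day, 0.873 between the days of the same strain and 0.849 where strain and day both differed. Strains resembled each other slightly more on day 27 (median 0.937 of 24 pairs) than on day 39 (median 0.913 of 24 pairs). The first principal component held 42.02% of the variance and parted the days. The next held 15.28% and set A15 apart from the other strains. The duplicates of 065 BP-8 on day 27 differed most, with 12.54% of genes more than 1.5-fold apart, against 3.21% to 6.18% in the other groups.

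**Figure D1:**
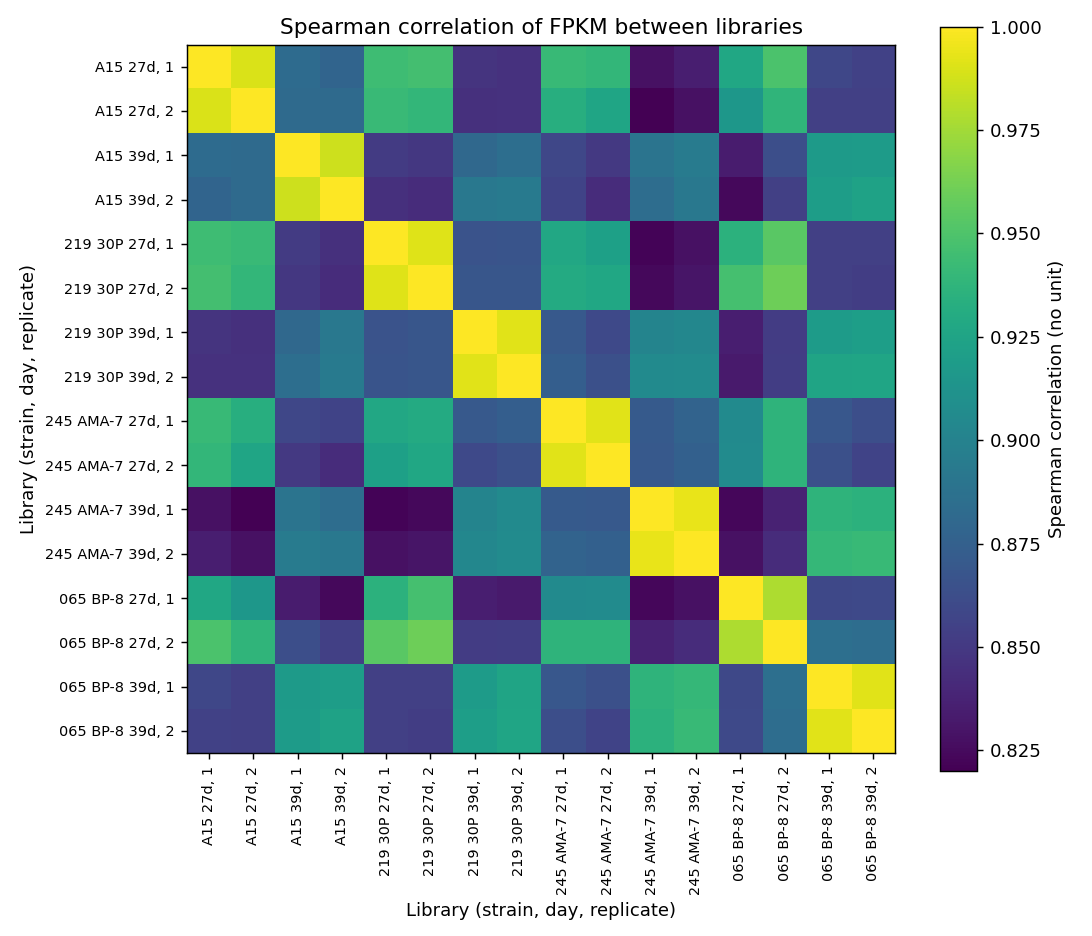
Spearman correlation between each pair of the 16 libraries across the genes tested, as a heat map with the libraries in order of group on both axes. Replicates of a group reach a median of 0.992, and libraries of the same day resemble each other more (medians 0.922 and 0.927) than libraries of the same strain on different days (0.873).

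The comparison of day 39 with day 27, averaged over the 4 strains, asked what changed in the mycelium between pinning and the first flush. Fet3 (AGABI2DRAFT_225781), a multicopper ferroxidase of iron uptake, rose in every strain, by 3.22 ± 0.08 (log2, SE) in the mean, a 9.32-fold change (limma, BH-adjusted p = 9.26e-12). Its mean level went from 8.59 to 178.57 FPKM in 245 AMA-7 and from 14.55 to 57.66 FPKM in 219 30P. Tco5 (AGABI2DRAFT_143539), a histidine kinase of two-component signalling, rose by 1.85 ± 0.07 (adjusted p = 2.98e-10). CytC2 (AGABI2DRAFT_135048), by its symbol a cytochrome c of the respiratory chain, fell by 1.98 ± 0.05 on the log2 scale, or 3.94-fold (adjusted p = 1.66e-11), from 1084.86 to 290.74 FPKM in A15. The heat shock gene hspC (AGABI2DRAFT_192819) fell by 1.52 ± 0.05 (adjusted p = 3.43e-11).

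Genes of oxidative phosphorylation mostly fell. Of the 50 subunit genes of complexes I to IV and ATP synthase that carry a symbol, 37 fell, 5 rose and 8 did not pass; adjusted over the list alone, 39 fell and 5 rose. All 5 genes of complex IV fell, as did all 5 of complex II, 9 of 10 of ATP synthase, 4 of 6 of complex III and 14 of 24 of complex I. Examples were RIP1 (the Rieske iron-sulfur protein of complex III, -1.17 ± 0.05), COX4 (complex IV, from 620.99 ± 4.82 to 305.70 ± 6.24 FPKM in A15, SD), SDH2 (complex II, -0.90 ± 0.05), ATP2 (the beta subunit of ATP synthase, -0.87 ± 0.05) and QCR1 (complex III, -0.82 ± 0.04). NdufA1 of complex I went the other way, with a rise of 0.62 ± 0.06 (adjusted p = 1.35e-06). NDE1, an NADH dehydrogenase outside complex I, fell by 0.91 ± 0.04. The whole list stood below other genes in the limma camera test with a preset correlation (adjusted p = 2.87e-05), as did ATP synthase (adjusted p = 0.00519) and complex IV (adjusted p = 0.0348). With an estimated correlation, none of these held (adjusted p = 0.955, 0.801 and 0.634). Complexes I, II and III did not pass with the preset correlation (adjusted p = 0.0783, 0.0747 and 0.121).

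In each strain more of the 50 genes fell than rose, as deposited and under both other scalings. In 219 30P 39 fell and 1 rose, and in 065 BP-8 32 fell and 2 rose; with median-ratio scaling these were 37 and 1, and 32 and 2. In A15 19 fell and 8 rose, and in 245 AMA-7 16 fell and 11 rose, which became 30 and 2, and 26 and 4, with median-ratio scaling. The list's median change was -0.69 in 219 30P, -0.35 in 065 BP-8, -0.13 in A15 and -0.11 in 245 AMA-7 as deposited, and -0.59, -0.42, -0.39 and -0.29 with median-ratio scaling. A difference between strains was not tested for the list. For the 24 genes of complex I the median was 0.12 in 245 AMA-7 as deposited and -0.06 with median-ratio scaling of the libraries, so that its sign there was not settled. In A15 the complex I median was -0.00, with 7 genes risen and 4 fallen, and with median-ratio scaling it was -0.25, with 2 risen and 10 fallen.

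**Figure D2:**
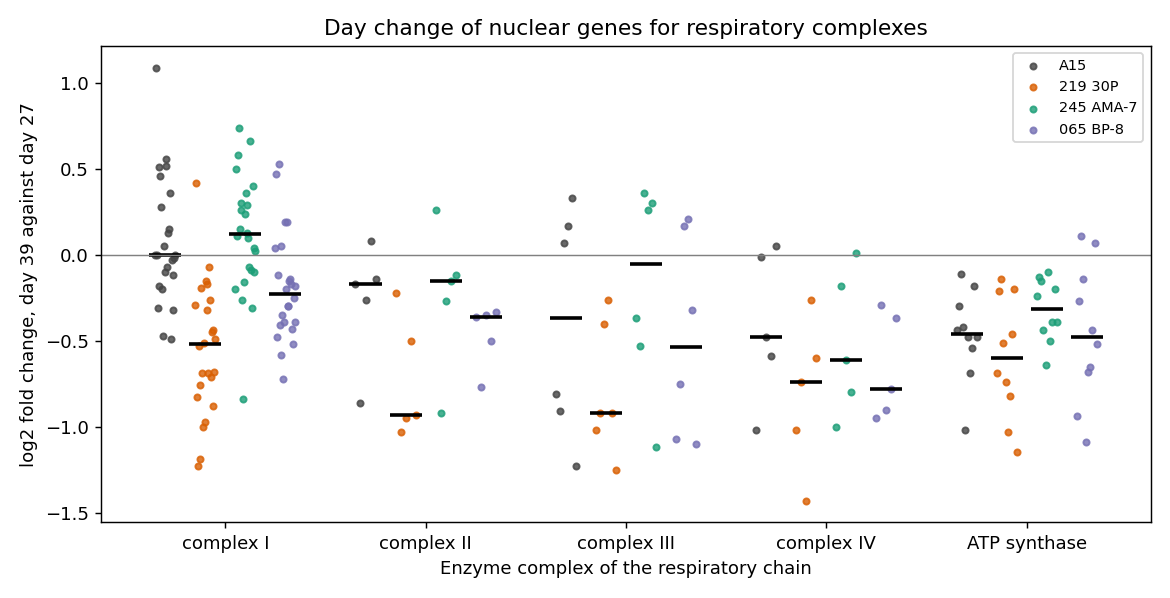
Change of each oxidative phosphorylation gene from day 27 to day 39 (log2 fold change, vertical axis) by complex and strain; points are genes and black lines medians. Most points lie under 0, with 39 of 50 genes fallen in 219 30P and 16 in 245 AMA-7 as deposited (37 and 26 with median-ratio scaling); the complex I median in 245 AMA-7 is 0.12 and turns to -0.06 with median-ratio scaling.

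Of the 5 genes found by the heat shock and chaperone list, 4 fell in the mean of the strains, hspC and hspA (-0.79 ± 0.06) among them. The list did not pass camera (adjusted p = 0.0741, and 0.634 with an estimated correlation). The exception, hspB (AGABI2DRAFT_133986), had a mean change of 0.06 (adjusted p = 0.713), and the strains went opposite ways, as they also did for hspE. The hspB gene fell in A15 (-1.13 ± 0.29), from 6511.59 to 2979.77 FPKM, and in 245 AMA-7 (-1.74 ± 0.29), from 10147.26 to 3045.48 FPKM. It rose by 1.45 ± 0.29 in 219 30P and by 1.65 ± 0.29 in 065 BP-8, the latter by 1.04 without replicate 1 of day 27. The mean fall of hspE (-0.26 ± 0.07) came with -1.22 in 245 AMA-7 and -0.33 in A15 against 0.35 in 219 30P (adjusted p = 0.038) and 0.17 in 065 BP-8 (adjusted p = 0.293), and its day effect differed between strains (adjusted p = 0.000114). In A15 and in 219 30P hspE did not pass once any single library of the strain was left out (adjusted p up to 0.229 and 0.154). Of the 7 genes of two-component signalling, 6 rose and SKN7, a response regulator, fell by 0.63 ± 0.08, a change of -0.36 without the 4 A15 libraries. That list did not pass camera (adjusted p = 0.157, and 0.801 with an estimated correlation).

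The largest changes of all were in genes without a name in the reference table, chosen here for their size after the values were seen. AGABI2DRAFT_134879 rose by 7.74 ± 0.29, from 2.01 to 2033.22 FPKM in 219 30P, and AGABI2DRAFT_190985 rose by 6.64 ± 0.22. AGABI2DRAFT_180174 fell by 6.06 ± 0.20, from 291.62 to 0.81 FPKM in A15.

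In the mean of the strains 6830 genes passed limma with BH adjustment, 3960 higher and 2870 lower on day 39, and 1625 of them changed at least 2-fold, 1048 up and 577 down. The share that rose among the genes called was 57.98% as deposited, 51.29% with median-ratio scaling and 47.47% with quantile normalization. The balance of rises and falls therefore rests on the scaling. Across strains 1155 genes rose in all 4 and 957 fell in all 4, against 131 and 46 if the strains' lists were independent, while 1385 genes passed in opposite directions in at least 2 strains. These counts used values as deposited, where the median change of all genes ran from -0.07 in 219 30P to 0.24 in A15. They were not repeated under the other scalings, so part of the opposite calls may rest on scaling.

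Laccases, the multicopper oxidases with which this fungus attacks lignin, and manganese peroxidase differed widely between strains. In 219 30P, lcc1 (AGABI2DRAFT_146228) fell 74.4-fold (-6.22 ± 0.40, adjusted p = 1.09e-07), from 1322.53 ± 775.36 to 15.27 ± 2.27 FPKM (SD, n = 2). It fell by 4.32 ± 0.40 in 065 BP-8 and fell by 2.85 ± 0.40 in 245 AMA-7. In A15 it stood at 486.95 ± 273.20 FPKM on day 27 and 682.71 ± 81.52 FPKM on day 39 (adjusted p = 0.209). The related lcc2 (AGABI2DRAFT_139148) fell in 219 30P (-3.59 ± 0.37), 065 BP-8 (-2.87 ± 0.37) and 245 AMA-7 (-1.59 ± 0.37), and was 1557.11 and 1735.91 FPKM in A15 (adjusted p = 0.544). Both differences between strains passed the test of a strain difference in the day effect, with adjusted p = 1.78e-05 for lcc1 and 0.000266 for lcc2. How the authors' counting divides reads between related laccase genes is not known, so the level of each alone is uncertain. The manganese peroxidase gene MnP (AGABI2DRAFT_221245) fell in all 4 strains, with -6.14 ± 0.35 in 219 30P, -2.50 ± 0.35 in A15, -2.42 ± 0.35 in 065 BP-8 and -2.26 ± 0.35 in 245 AMA-7.

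Other laccases rose. In 245 AMA-7, lcc9 rose by 3.30 ± 0.31 and lcc10 by 3.02 ± 0.29, and in 065 BP-8 by 1.37 and 1.12. Neither passed in A15 or 219 30P as deposited, but lcc9 passed in 219 30P with median-ratio scaling (0.76, adjusted p = 0.0498) and quantile normalization (0.74, adjusted p = 0.0434). Another gene, lcc3, rose by 2.19 ± 0.18 in 219 30P, by 1.56 ± 0.18 in 245 AMA-7 and by 1.45 ± 0.18 in A15, where quantile normalization gave 0.95, and did not pass in 065 BP-8 (0.33, adjusted p = 0.133). In 065 BP-8, lcc12 passed with a fall of 2.34 ± 0.96 (adjusted p = 0.0496), but its day 27 level was 345.89 ± 441.63 FPKM (SD, n = 2). Without replicate 1 of that day the change was -0.21 (adjusted p = 0.757), and without replicate 2 it was -4.46. In the mean of the strains 3 of the 6 laccases rose and 2 fell, and the list's median (0.90) and mean (-0.09) differed in sign. The camera test pointed up without passing (adjusted p = 0.899, and 0.955 with an estimated correlation).

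**Figure D3:**
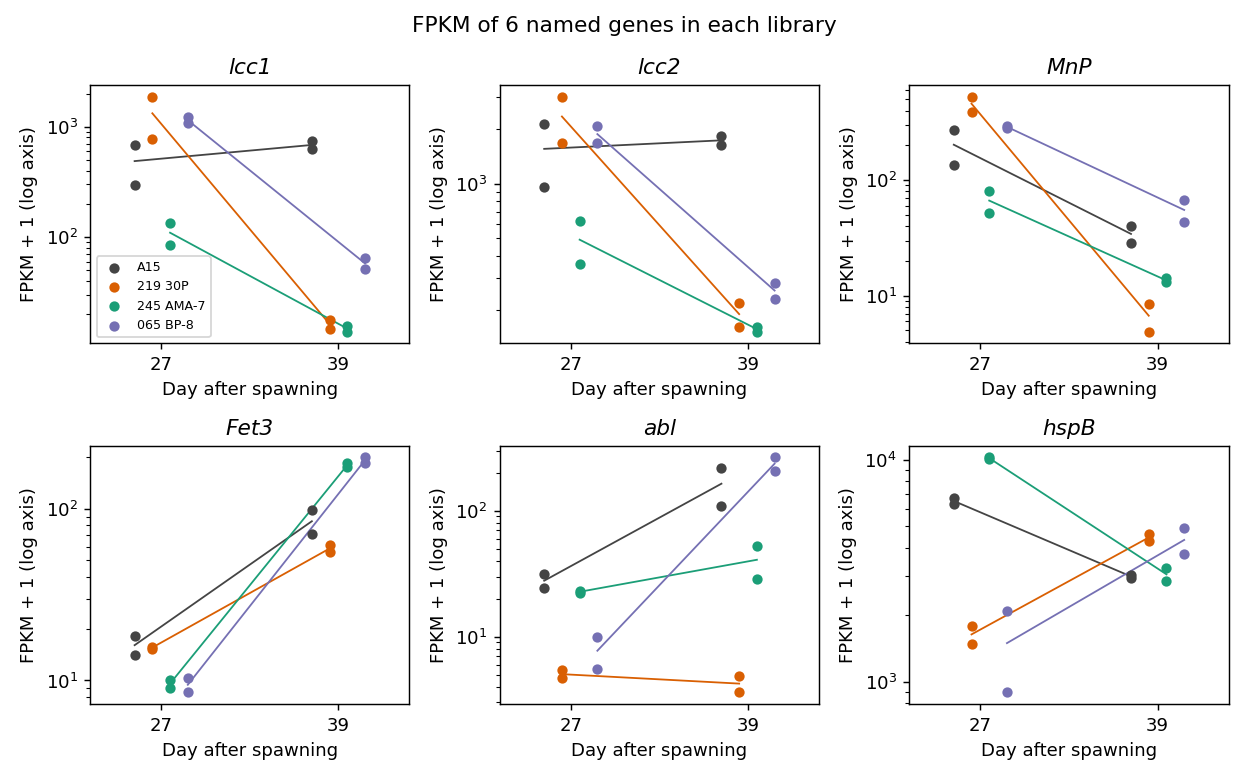
Levels of lcc1, lcc2, MnP, Fet3, abl and hspB in each library (FPKM + 1, log axis) on days 27 and 39 by strain; points are libraries and lines join group means. In lcc1 and lcc2 the A15 lines do not fall while those of the other strains do, lcc1 from 1322.53 to 15.27 FPKM in 219 30P, and Fet3 rises in each strain.

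Within A15 the named genes with the largest rises were abl, Fet3, Tco5 and lcc3. The gene abl (AGABI2DRAFT_194888), which carries the symbol of the A. bisporus lectin, rose by 2.49 ± 0.36 (adjusted p = 7.58e-05), from 26.80 to 162.86 FPKM. Fet3 rose by 2.39 ± 0.16 and Tco5 by 1.47 ± 0.15. Among named genes the largest falls were in MnP (-2.50 ± 0.35), CytC2 (-1.89 ± 0.11), SKN7 (-1.46 ± 0.16) and hspC (-1.35 ± 0.09). In A15 5497 genes passed, 3645 higher and 1852 lower, of which 1624 and 532 changed at least 2-fold. Rises made up 66.31% of the genes called as deposited, but 49.20% with median-ratio scaling and 45.71% with quantile normalization. The median change of all genes was 0.24 as deposited, and median-ratio scaling moved it to 0.00.

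Among named genes that met the selection rule, lcc3 (2.19 ± 0.18) and Fet3 (1.91 ± 0.16) rose most in 219 30P. The histidine kinase gene STK/HK (1.79 ± 0.15) and Tco5 (1.70 ± 0.15) came next. The falls were led by lcc1, MnP, lcc2 and CytC2 (-1.86 ± 0.11). The phenylpropanoid gene C4H1 rose by 2.01 ± 0.32 in this strain, but at 8.82 FPKM on day 39 it stayed below the level the rule requires. There abl was 4.04 FPKM on day 27 and 3.24 FPKM on day 39 (adjusted p = 0.548). In this strain 5506 genes passed, 2436 higher and 3070 lower, with 980 and 1112 at least 2-fold.

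Among named genes in 245 AMA-7, Fet3 rose most, 18.7-fold (4.23 ± 0.16), followed by lcc9, lcc10 and Tco5 (2.85 ± 0.15). The largest fall among named genes was in met2, named for homoserine acetyltransferase of methionine synthesis, at -3.26 ± 0.30, or -1.91 with a pseudocount of 5. Then came lcc1, CytC2 (-2.49 ± 0.11) and AOX, an alternative oxidase, with -2.35 ± 0.49 (adjusted p = 0.00109). Here 5557 genes passed, 3329 higher and 2228 lower, with 1385 and 796 at least 2-fold. Rises were 59.91% of them as deposited, 48.51% with median-ratio scaling and 48.89% with quantile normalization.

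In 065 BP-8, abl rose 31.7-fold (4.99 ± 0.36, adjusted p = 2.54e-07), from 6.72 to 235.41 FPKM, and Fet3 20.4-fold (4.35 ± 0.16). Among named genes that met the selection rule they were followed by hspB and Tco5 (1.37 ± 0.15), and the falls were led by lcc1, lcc2, MnP and lcc12. In this strain 5524 genes passed, 3046 higher and 2478 lower, with 1261 and 848 at least 2-fold.

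A test of whether the day effect differed between strains passed for 6237 genes, 3153 of them with a difference of at least 2-fold between a strain and A15. The named genes with the smallest adjusted p were Fet3 (1.07e-05), lcc1 (1.78e-05), abl (3.51e-05), NdufA4 (4.34e-05), hspB (5.04e-05) and MnP (9.81e-05). For NdufA4 of complex I the day effect in 219 30P was below that in A15 by a log2 difference of -1.01, or -0.66 with median-ratio scaling. RIP1 and COX4 of complexes III and IV did not pass this test (adjusted p = 0.642 and 0.917). Across all genes the day effects of pairs of strains correlated with Pearson's r of 0.55 to 0.71 (Spearman 0.54 to 0.70), a description across genes with no test. Of the genes called in both strains of a pair, 81.97% to 93.13% moved the same way.

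The comparisons with A15 asked how the other strains differed from the commercial strain at each stage. The A15 files list fewer genes than the others and in another order, so strain and table cannot be separated in any of these comparisons. The same 2 A15 libraries also serve all 3 comparisons of a day.

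In 219 30P, abl was lower than in A15 on both days, with -2.46 ± 0.36 on day 27 (4.04 against 26.80 FPKM) and 36.9-fold on day 39 (-5.20 ± 0.36, adjusted p = 3.51e-07). COX5B of complex IV was lower (-0.60 ± 0.11 and -1.56 ± 0.11), as was PhrB, named for a DNA photolyase (-0.61 ± 0.14 and -1.15 ± 0.14). The gene met2 was lower on day 27 (-2.10 ± 0.30); its day 39 difference (15.09 against 32.05 FPKM, adjusted p = 0.0129) did not pass without replicate 2 of A15 (-0.66) or of 219 30P (-0.87) of that day. CytC2 was higher on both days (0.45 ± 0.11 and 0.48 ± 0.11), and so was NDE1 (0.46 ± 0.09 and 0.39 ± 0.09, the latter 0.59 with median-ratio scaling and 0.65 with quantile normalization). On day 39, lcc1 was lower (-5.39 ± 0.40). On day 27 it was higher by 1.43 (adjusted p = 0.0138), a call lost without replicate 1 of A15 (0.82) or of 219 30P (0.79) of that day.

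On day 39, 6 of the 7 two-component genes were higher in 219 30P than in A15 (camera adjusted p = 0.00519, and 0.585 with an estimated correlation). Of the 50 oxidative phosphorylation genes 33 were lower and 1 higher (adjusted p = 0.0348), 20 of them among the 24 genes of complex I (adjusted p = 0.00893). Both had adjusted p = 0.955 with an estimated correlation, and median-ratio scaling left 19 of the 50 lower and 7 higher. In 219 30P, 3668 genes passed on day 27, 2422 higher and 1246 lower, and 5268 on day 39, 1715 higher and 3553 lower. At least 2-fold were 472 higher and 499 lower on day 27, and 574 and 1318 on day 39. The share of higher genes was 66.03% on day 27 and 32.56% on day 39 as deposited. It became 48.65% and 49.20% with median-ratio scaling, and 55.42% and 50.54% with quantile normalization.

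In 245 AMA-7, lcc1 was lower than in A15 on both days, with -2.07 ± 0.40 on day 27 and 46.1-fold on day 39 (-5.53 ± 0.40, adjusted p = 5.19e-07). The gene met2 was lower, with -2.06 ± 0.30 on day 27 and 17-fold on day 39 (0.92 against 32.05 FPKM, a log2 difference of -4.09, or -2.62 with a pseudocount of 5), as was COX5B (-0.86 ± 0.11 and -0.99 ± 0.11). CAT3, a catalase, was higher by 1.11 ± 0.15 and 1.62 ± 0.15 (the former 0.72 with a pseudocount of 5), NDE1 by 0.75 ± 0.09 and 0.78 ± 0.09, and the histidine kinase gene Tco6 by 0.79 ± 0.12 and 1.17 ± 0.12. The gene lcc2 was lower on day 39 (-3.47 ± 0.37). Its day 27 difference of -1.61 did not pass without replicate 2 of A15 (-1.03) or of 245 AMA-7 (-1.21) of that day. On day 39, 5 two-component genes were higher (camera adjusted p = 0.013, and 0.585 with an estimated correlation). In 245 AMA-7, 3493 genes passed on day 27, 1963 higher and 1530 lower, and 4732 on day 39, 2150 higher and 2582 lower. At least 2-fold were 455 higher and 560 lower on day 27, and 565 and 972 on day 39.

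In 065 BP-8, met2 was lower than in A15 on both days (-3.15 ± 0.30 on day 27 and -2.14 ± 0.30 on day 39), as were PhrB (-1.19 ± 0.14 and -0.98 ± 0.14) and lcc9 (-2.12 ± 0.31 and -1.26 ± 0.31). The day 39 call of lcc9 was lost without replicate 1 of 065 BP-8 of that day (-1.05, adjusted p = 0.0512). Tco5 was higher (0.85 ± 0.15 and 0.75 ± 0.15). CytC2 was higher too (0.63 ± 0.11 and 0.86 ± 0.11), as was NDE1 (0.43 ± 0.09 and 0.75 ± 0.09); a fit on the 4 libraries of day 27 alone gave adjusted p = 0.0586 and 0.0611 for that day. On day 39, lcc1 was lower (-3.57 ± 0.40), and 4 two-component genes were higher (camera adjusted p = 0.0452, and 0.634 with an estimated correlation). On day 27 lcc1 was higher by 1.35, a call lost without replicate 1 of A15 (0.75) or of 065 BP-8 (1.26) of that day. In 065 BP-8, 3799 genes passed on day 27, 2295 higher and 1504 lower, and 4073 on day 39, 1572 higher and 2501 lower. At least 2-fold were 406 higher and 595 lower on day 27, and 435 and 825 on day 39. On day 27 the count fell to 2415 without replicate 2 of A15, and on day 39 the share of higher genes, 38.60%, became 48.92% with median-ratio scaling and 52.43% with quantile normalization.

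Some unnamed genes had very low values in either A15 or the other strain of a comparison. Sequence that differs from the reference could also give low values, which was not examined. AGABI2DRAFT_121073 stood at 62.07 and 68.43 FPKM in A15 on days 27 and 39 and at 0.07 FPKM on both days in 065 BP-8 (adjusted p = 3.3e-10 and 6.35e-10). AGABI2DRAFT_191018 stood at 381.59 and 466.43 FPKM in A15 and at 0.51 and 0.28 FPKM in 065 BP-8 (adjusted p = 1.17e-05 and 5.13e-06). In 219 30P, AGABI2DRAFT_117638 was at 23.72 and 14.97 FPKM against 0.10 and 0.26 FPKM in A15 (adjusted p = 1.33e-09 and 5.26e-09). The fitted fold of such genes depends on the pseudocount and is not given.

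Some genes differed from A15 in all 3 strains. On day 27, 562 genes were higher and 382 lower in all 3 strains, and on day 39, 618 and 1238. The 3 comparisons use the same A15 libraries, so these lists are not independent. In 20 simulations with no strain difference and the A15 libraries shared, a mean of 0.00 genes were called in all 3 comparisons in either direction on each day. With no gene changed, hardly any is called in a single comparison, so that count cannot show how far shared libraries raise the overlap. The differences from A15 correlated between strains with a mean r across genes of 0.48 on day 27 and 0.60 on day 39, against 0.50 in the simulations, and their mean covariance was 0.269 and 0.474, against 0.024. A difference common to the A15 libraries or their files was not part of the simulations. SKN7 was higher than in A15 in all 3 strains on day 39 (1.26, 1.53 and 1.35, each ± 0.16). None of the 63 camera tests, over 9 lists and 7 contrasts, held with an estimated correlation (lowest adjusted p = 0.585).

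**Figure D4:**
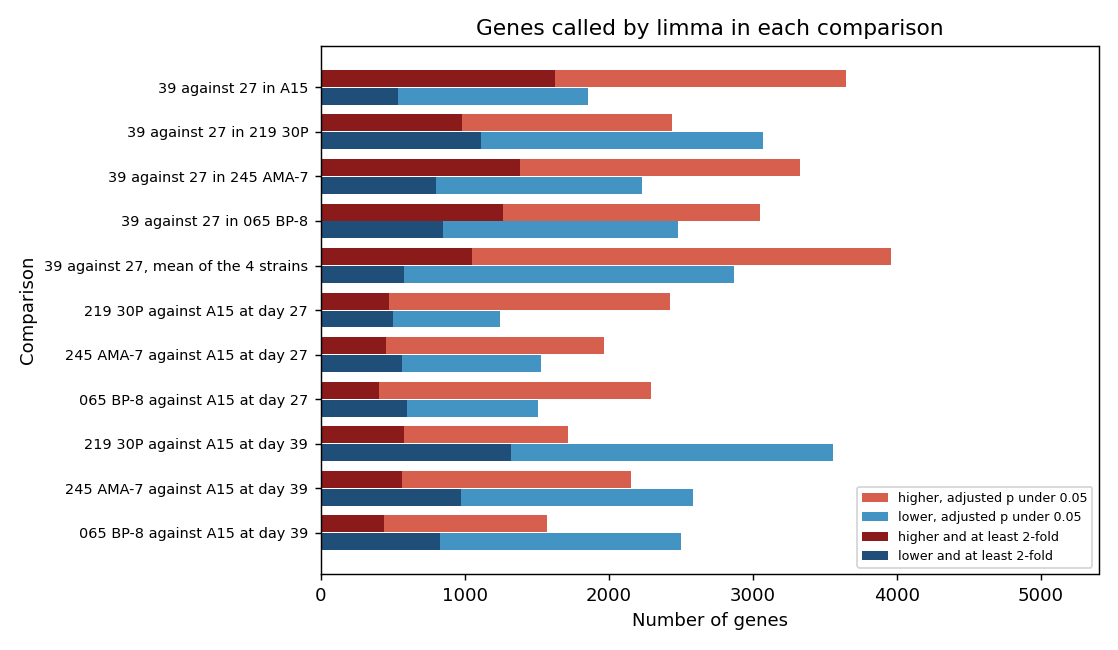
Number of genes higher and lower at adjusted p under 0.05 (limma, BH) in each of the 11 comparisons, as bars from 0, with the part changed at least 2-fold in a darker shade. The counts range from 3493 genes for 245 AMA-7 against A15 on day 27 to 6830 for the days in the mean of the strains.

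The 3 non-A15 strains, whose files list the same genes, were also compared with each other. The gene abl differed most among the named genes, with a range of strain means of 3.18 (log2, adjusted p = 1.08e-06), highest in 065 BP-8 on day 39 at 235.41 FPKM and at 3.24 FPKM in 219 30P. It was followed by lcc1 (2.69, adjusted p = 1.82e-05) and by lcc12 (2.35, adjusted p = 0.0188). The range of lcc12 was 1.28 without replicate 1 of 065 BP-8 on day 27, and without replicate 2 of that strain on day 39 the call was lost (adjusted p = 0.0562). Next were MnP (2.07, adjusted p = 4.96e-05), CAT3 (1.52, adjusted p = 5.81e-07), highest in 245 AMA-7, and met2 (1.52, adjusted p = 0.000155; 0.86 with a pseudocount of 5). In this test 6158 genes passed limma with BH adjustment, 1476 of them with a range of at least 2-fold.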

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

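Among the tests below, those of a wrong A15 day label and of reads moving between lcc1 and lcc2 were chosen only after the result was seen.

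The laccase genes lcc1 and lcc2 fell between the days in 219 30P, 245 AMA-7 and 065 BP-8 and did not pass in A15, and the day effect in 219 30P minus A15 was -6.82 for lcc1 and -3.85 for lcc2 (log2). A wrong label on the A15 day 39 libraries is argued against, since their median Spearman correlation with day 39 libraries of the other strains exceeded that with day 27 libraries by at least 0.042. Reads moving between lcc1 and lcc2 alone cannot lower both; the sum of both on day 39, at most 0.284 times the day 27 sum in the other strains and 1.183 in A15, restates this fall and is no separate test, and sharing with further laccase genes was not examined. A programme slowed alike for all genes in A15 is argued against by 685 genes changed at least 2-fold one way in the other strains. Their A15 change was a median 0.78 of that in the others (quartiles 0.56 and 1.06), whereas for lcc1 and lcc2 this ratio was -0.14 and -0.10. A smaller lag in A15 with a late fall of lcc1 and lcc2 cannot be excluded by this median, which used values as deposited. A strain difference in laccase regulation stays open and was not tested.

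On both days together, each other strain had more genes at least 2-fold lower than A15 than higher: 312 against 118 in 219 30P, 343 against 132 in 245 AMA-7 and 303 against 109 in 065 BP-8. The genes absent from the A15 files do not account for it, since with those genes at 0 in A15 the lowest ratio of lower to higher genes was 2.45, against 2.60 as deposited. Scaling does not either, with a lowest ratio of 2.76 under median-ratio scaling. Sequence that differs from or is missing relative to the reference strain stays open. Among genes tested, lower genes were under 0.5 FPKM in all 4 libraries of the strain more often than higher genes were in A15. The gap was at least 3.62 percentage points (16.67% against 8.47% in 219 30P), too little to decide. Genes absent from the A15 files were left out of it. With them at 0 in A15, the higher genes in 245 AMA-7 went from 132 to 140 and the lower ones stayed at 343. The gap there (11.95% against 8.33%) was not computed with them, so its direction is not settled. Differing or missing sequence, a biological strain difference and the separate making or filtering of the A15 tables cannot be told apart with these files. The genomes of the strains were not used here. The checks of absent genes and of scaling do not cover differences gene by gene in how the A15 values were made.

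In A15 more genes rose (3645) than fell (1852) between the days. A smaller share for a few abundant genes on day 39 may contribute, since the 50 most abundant genes went from 28.09% to 24.67% of FPKM in A15, and without them the median change of the other genes was 0.15 in place of 0.24, a ratio of 0.64. That ratio lies between the bounds set for it, so this effect cannot be told apart from a wider rise across genes. FPKM are relative to each library's total, so a change in the amount of RNA per cell was not measurable.

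The day effect differed between strains for 6237 genes by limma's F test. Of 100 splits that exchanged libraries between strains within each day, the real one included, only the real split gave as many genes, and the highest other gave 1535. For the days in the mean of the strains, 100 splits within strains gave 6830 genes for the real split alone and 4635 at most for the others. The split with 4635 genes kept 6 of 8 replicate pairs together. It was among 15 splits other than the real one that passed 100 genes. Among the 3 non-A15 strains, only the real split of 100 gave 6158 genes, and the highest of the other splits gave 5599. That other split kept the replicates of each group of these strains together. It exchanged whole groups and so carries strain and group differences of its own. In all, 33 of the other splits passed 100 genes. In each of these 3 sets, splits that part duplicates gain spread within groups, since duplicates are much alike and may be technical in part. The counts show that libraries regrouped at random gave fewer genes. They cannot exclude chance differences between groups or crates.

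Other genes named for the days also had a day effect that differed between strains past the F test. Each value here is the day effect in a strain minus that in A15, on the log2 scale. For each gene only the strain with the largest absolute difference is given, and the F test does not single out that strain. In 065 BP-8 it was 1.96 for Fet3, 2.78 for hspB, -1.12 for lcc3, -3.37 for lcc12 and -0.88 for PAL2. The hspB and lcc12 values in that strain rest on day 27 duplicates that lie far apart: without replicate 1 of that day their change between the days in this strain was 1.04 and -0.21. By the changes given above, Fet3 in 245 AMA-7 and hspB in 219 30P differed from A15 in the same direction and nearly as much. In 245 AMA-7 it was 1.38 for Tco5, -0.60 for CytC2, -0.36 for hspC, 0.38 for ATP2, 0.43 for QCR1, 2.79 for lcc9, 2.62 for lcc10, 1.28 for PAL1 and -0.89 for hspE. Unnamed genes in 245 AMA-7 had 2.50 (AGABI2DRAFT_190985) and 2.88 (AGABI2DRAFT_180174). In 219 30P it was -0.67 for NdufA1, -0.62 for hspA, -3.64 for MnP, -2.75 for abl, 1.26 for C4H1 and 3.22 for AGABI2DRAFT_134879. Scaling matters for the small differences: NdufA1 had -0.32 with median-ratio scaling (adjusted p = 0.0963 in the F test) and -0.42 with quantile normalization (adjusted p = 0.0774), so it passed under neither. With median-ratio scaling hspA had -0.26 and did not pass (adjusted p = 0.0771). With quantile normalization lcc12 did not pass (adjusted p = 0.0501), and hspC had -0.24 and ATP2 0.61.

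Of the genes that the A15 files do not list, which the comparisons of the report left out, 16 had a mean of 1 FPKM or more in the 12 other libraries.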

How the results depend on the processing

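Only keeping the genes absent from the A15 files at 0 was chosen after the data were seen. Of 13 counts of genes, all but 1 stayed within 1.5 times the reported value under the alternatives, apart from a fold threshold of 2. That threshold by construction left 2156, 2092, 2181 and 2109 genes for the days in A15, 219 30P, 245 AMA-7 and 065 BP-8, and 1625 for their mean. Against A15 it left 971, 1015 and 1001 genes on day 27 and 1892, 1537 and 1260 on day 39, in the same order of strains. It left 1476 among the non-A15 strains and 3153 for the strain difference in the day effect. The exception, 065 BP-8 against A15 on day 27, gave 1825 genes in a fit on its 4 libraries, which has fewer degrees of freedom. Leaving out 1 library at a time, with the lone library of a group assumed to vary like the others, gave 2415 (without replicate 2 of A15) to 3855 genes there; the cause of that low count was not tested. For the mean of the strains it gave 6619 to 6847 genes.

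Median-ratio scaling brought the median change of all genes from 0.24, 0.16 and 0.11 to 0.00, 0.00 and 0.02 for the days in A15, in 245 AMA-7 and in the mean. Against A15 it went from 0.15 to 0.01 in 219 30P on day 27, from -0.22 to -0.02 in 219 30P on day 39 and from -0.12 to -0.03 in 065 BP-8 on day 39. Gene changes read relative to these shifts where the balance of directions matters. Of 426 results for named genes 357 were never weakened by the alternatives run for them, and 0 reversed. A result that had not passed could not be weakened, and list members were included whether or not they passed. Most other named genes had been chosen for passing without overlap. Median-ratio scaling weakened 16 of 426, quantile normalization 14, and a fit on the 4 libraries compared 32 of 359. Leaving out a library weakened 224 of 6816, a total that also counts libraries outside the groups compared. A replicate block gave 6836 genes for the mean of the strains, and a block within strain 6737. Camera's calls for oxidative phosphorylation, ATP synthase and complex IV in the mean of the strains ended with an estimated correlation (adjusted p = 0.955, 0.801 and 0.634). Count-based alternatives (DESeq2, edgeR) were not run, since the files hold no counts.

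Depth limits genes near 0.113 to 0.128 FPKM, the level of 1 read in a gene of 1 kilobase, where differences were not detectable.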

Other observations

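No test in this part was chosen after its result was seen; the genes singled out by size or level were.

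The phenylpropanoid enzymes moved apart between the days. PAL1 and PAL2 carry the symbol of phenylalanine ammonia-lyase, which releases cinnamate from phenylalanine. In the mean of the strains PAL1 rose by 0.91 ± 0.08 (log2, SE; adjusted p = 4.15e-07) and PAL2 fell by 1.10 ± 0.11 (adjusted p = 1.2e-06). PAL2 fell in each strain, most in 065 BP-8, from 389.80 to 112.19 FPKM, and PAL1 rose most in 245 AMA-7, from 226.48 to 706.80 FPKM, and did not pass in A15 (0.35, adjusted p = 0.0822). The fall of PAL2 in 219 30P (-0.82) did not pass without replicate 2 of day 27 (-0.67) or without replicate 1 of day 39 (-0.66). C4H1, the remaining gene of this group, rose by 0.64 ± 0.16 in the mean (0.32 with a pseudocount of 5), at low levels outside 219 30P on day 39 (8.82 FPKM). Within strains C4H1 passed in 219 30P alone, at 2.01 ± 0.32, with 0.75 in A15, 0.11 in 245 AMA-7 and -0.32 in 065 BP-8, and its day effect differed between strains (adjusted p = 0.00318). Of the catalases CAT3 rose by 0.70 ± 0.08 in the mean (0.41 with quantile normalization), with 0.98 in 219 30P and 1.01 in 245 AMA-7. It did not pass in 065 BP-8 (0.32, adjusted p = 0.0829). In A15 it passed as deposited (0.51), but not with median-ratio scaling (0.29) or quantile normalization (-0.05). The day effect of CAT3 differed between strains (adjusted p = 0.0243). CAT1 had 0.14 ± 0.08 in the mean (adjusted p = 0.132), with 0.23 (adjusted p = 0.0438) without the A15 libraries and -0.14 with quantile normalization. In the group of alternative respiration AOX fell by 1.29 ± 0.24 and NDE1 by 0.91 ± 0.04, and NDE2 had 0.07 ± 0.06 (adjusted p = 0.322). Within strains AOX passed in 245 AMA-7 (-2.35) and did not in 219 30P (-0.24, adjusted p = 0.683). In A15 it did not pass as deposited (-0.98, adjusted p = 0.0983) and passed with median-ratio scaling (-1.23, adjusted p = 0.0443) and quantile normalization (-1.22, adjusted p = 0.041). In 065 BP-8 it passed (-1.61), but its day 27 duplicates lie far apart, at 151.76 ± 141.85 FPKM (mean and SD), and without replicate 1 of that day it had -0.47 (adjusted p = 0.0579). The test of a strain difference in the day effect of AOX did not pass as deposited (adjusted p = 0.07) and did with the other scalings (adjusted p = 0.0475 and 0.0403).

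The most abundant transcript in 13 of 16 libraries was AGABI2DRAFT_136557, which held 9.20% and 10.48% of all FPKM in the day 27 libraries of 065 BP-8. Of the 3 highest genes absent from the A15 files, 2 were expressed in a single other strain and the last in more. AGABI2DRAFT_58707 stood at 29.55 and 76.44 FPKM in 245 AMA-7 on days 27 and 39, and at 0.17 FPKM or less in the groups of 219 30P and 065 BP-8. AGABI2DRAFT_123399 stood at 63.04 and 6.58 FPKM in 065 BP-8 and was listed at 0 in 219 30P and 245 AMA-7. AGABI2DRAFT_71082 stood at 13.71 and 15.54 FPKM in 219 30P, 29.04 and 6.33 FPKM in 065 BP-8, and 0.37 and 1.26 FPKM in 245 AMA-7.

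One hypothesis was that genes differing from A15 lie side by side in the genome. Neighbours were taken as successive genes among the 8759 tested and placed ones, so untested genes may lie between them. The 644 genes at least 2-fold lower than A15 on both days in 1 or more strains formed 125 neighbouring pairs in the gene order of Agabi_varbisH97_2, against a mean of 47.15 in 100000 random orders of 8759 genes (one-sided permutation p = 1e-05, the smallest these can give). The longest run held 6 genes, from AGABI2DRAFT_142061 to AGABI2DRAFT_177468. The 281 genes at least 2-fold higher formed 32 pairs against 8.95 (one-sided permutation p = 1e-05). Neighbouring genes may therefore share the difference, which would also be seen if stretches of sequence were missing or diverged in a strain; the test does not part these.

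The same was asked of the days. The 1147 placed genes that rose in all 4 strains formed 199 neighbouring pairs against a mean of 149.63 in random orders, and the 951 that fell formed 150 against 102.90 (one-sided permutation p = 1e-05 for each, the smallest possible). Genes that changed together between pinning and first flush may thus be neighbours more often than random order gives. Related genes in tandem, which can share reads, were not told apart from co-regulation.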
